A study of Homo sapiens with 9 samples.

How the data were processed

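Total RNA of A2780 cells was extracted with a column kit and 1.3 ug went into a mRNA library kit, per the labels' protocols. The sources record 3 DMSO, 3 cisplatin and 3 Pt-ttpy libraries. The drug written "Cispt" in the labels was read as cisplatin. The authors deposited 1 table of counts per gene for the 9 libraries, and every column of counts belongs to a sample. Reads were placed on GRCh38, per the submitters' processing notes. The aligner, the counting program and the strandedness of the counting are not given in the sources used here. Of 24542 genes and loci, 19974 carried Ensembl gene identifiers, all of them in GENCODE 29 and 19922 protein-coding there, and 4568 were named newGene with no position. The newGene loci were kept, and held 1.56% to 2.18% of a library's counts. Symbols were known for 19413 of the Ensembl genes. Library totals ranged from 31.3 to 40.8 M counts, with means of 38.2 ± 2.34 M for DMSO, 34.6 ± 4.31 for cisplatin and 33.6 ± 1.36 for Pt-ttpy (SD, n = 3). The 10 genes with the most counts held 4.19% to 6.07% of a library.

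Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10), scaled with TMM factors and fitted with robust quasi-likelihood models, with 1 mean per group over all 9 libraries. The 3 contrasts were Pt-ttpy vs DMSO, cisplatin vs DMSO and Pt-ttpy vs cisplatin. Changes were called at a Benjamini-Hochberg adjusted p under 0.05, over the 15558 genes of each contrast. All p-values of single genes are from edgeR's quasi-likelihood F test and are adjusted unless called unadjusted. Fitted log2 changes used a prior count of 0.125. CPM values are counts scaled to library size with TMM factors. The gene lists, contrasts, tests, genes chosen in advance and most alternatives were fixed before the data were examined. The explanations weighed in the closing section for the p53, hypoxia, glycolysis and mitochondrial patterns were set after these patterns had been seen.

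The genes named are, for each contrast, the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 5 CPM in either group and no overlap between the values of the groups, 39 genes chosen in advance, and up to 4 members per list by adjusted p. A called gene was checked in 9 further fits, each without 1 library. Exon overlaps come from GENCODE 29. A few genes that meet this rule are not reported here.

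The 37 lists were written from general knowledge. They cover the 13 genes of mitochondrial DNA, nuclear respiratory subunits (complex I, complexes II to V), the citrate cycle, mitochondrial ribosomal proteins, mitochondrial chaperones, factors of mitochondrial DNA and mitophagy. They cover p53 targets, apoptosis, 4 classes of DNA repair and cell cycle, G-quadruplex helicases and promoter genes, telomeres, ribosome biogenesis, ribosomal proteins and histones. They also cover glycolysis, hypoxia, integrated stress response, heat shock, NRF2, metallothioneins, cholesterol, lysosome, NF-kB, interferon, extracellular matrix and markers of other cell types. The erythroid markers, 0 of 11 tested, fell under the minimum of 3 tested genes, so 36 lists were tested in each of 3 contrasts, adjusted within the contrast. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts of members over the list alone use p-values adjusted within that list. The intervals of list means are t intervals (95%) over the library means of each list.

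The mitochondrial share was tested by exact permutation of 3 against 3 libraries, two-sided, and its 3 p-values were adjusted together. The 95% intervals of single shares are exact binomial (Clopper-Pearson) intervals. The effect of the shared controls on correlation and overlap was simulated 20 times. The recovery of planted changes was tested on simulated counts. Transcript GC content was known for 13383 tested genes (86.0%). No libraries were duplicates of each other.

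Other settings chosen in advance were DESeq2 1.42.0 (its size factors, and its Wald test), limma-voom, upper-quartile factors, library totals, library sizes without mitochondrial genes, other filters and thresholds, a fit without robust estimation, the 6 libraries of a contrast alone, and each library left out. A fit without DMSO 2 and cisplatin 2 (7 libraries), a correction for GC content (lowess span 0.3) and a fit without newGene loci were added after the GC trend and the loci had been seen. The planned test of G-quadruplex motifs in promoters was left out because no genome sequence was at hand.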

Results

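RNA was sequenced from A2780 cells, a line derived from a human ovarian carcinoma, after 96 h with 0.5% DMSO, with cisplatin at 0.6 µM or with Pt-ttpy at 5.5 µM. Cisplatin is a platinum drug that crosslinks DNA. Pt-ttpy is a platinum complex that the series title describes as binding G-quadruplexes, which are folded structures of guanine-rich DNA or RNA, and as disturbing mitochondria. Each group held 3 libraries labelled as biological replicates, 9 in all, and the labels place each drug at its IC80. The count table held 24542 genes and loci, of which 15558 passed the filter on low counts and were tested. The 3 DMSO libraries, named DMSO 1, 2 and 3 by replicate number, held 36.4, 37.3 and 40.8 M counts. The cisplatin libraries held 31.3, 39.5 and 33.1 M, and the Pt-ttpy libraries held 32.4, 35.1 and 33.4 M. The first principal component carried 36.6% of the variance and separated the DMSO libraries from all treated libraries, with cisplatin farther from DMSO than Pt-ttpy. The second carried 15.9% and separated DMSO 2 and cisplatin 2 from the other 7. In these 2 libraries counts rose with the GC content of the transcript (Spearman rho with the deviation from the mean of all libraries 0.51 and 0.41). In the other 7 libraries rho lay between −0.34 and −0.16. Nothing in the labels says whether the replicates were separate cultures, and if they were not, the p-values below measure only the spread between these samples.

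The comparison of Pt-ttpy with DMSO asked which genes respond to Pt-ttpy, the question the design sets for finding its targets. After 96 h with Pt-ttpy, part of the p53 target genes (14 of 47) and of the genes induced by low oxygen (9 of 23) were higher. Lower were part of the nuclear genes for the mitochondrial ribosome (26 of 77), ribosome assembly (10 of 36) and chaperones (8 of 27). As lists these were called by camera at its preset correlation and not with an estimated correlation (adjusted p = 0.293 for each). Of the 15558 genes tested, 1874 changed, 870 higher and 1004 lower, and 4637 had an unadjusted p under 0.05. At least 2-fold changes were found in 374 genes, 341 higher and 33 lower. Of the called loci, 160 carried only the name newGene, 151 of them higher. The division between rises and falls depended on the scaling. With upper-quartile factors 1050 genes were higher and 666 lower, and with library totals alone 1005 were higher and 773 lower. It also changed with 1 Pt-ttpy library left out, to 199 higher and 68 lower without Pt-ttpy 1. The counts were 143 and 42 without Pt-ttpy 2, and 212 and 87 without Pt-ttpy 3. Such fits leave 2 libraries in the Pt-ttpy group and have less power, so the loss of calls need not trace to any 1 library. Fewer libraries did not always mean fewer calls, with 3004 without cisplatin 2 and 5189 without DMSO 2 and cisplatin 2.

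Among the 8 largest rises of genes with at least 5 CPM in either group, PDE4C, a phosphodiesterase of cyclic AMP, was near absent with DMSO. Its counts in the DMSO libraries were 0, 12 and 1, against 235, 189 and 154 with Pt-ttpy, so its fitted log2 change of 5.55 depends on the prior count. ACSM3, an acyl-CoA synthetase of the mitochondrial matrix, rose from 3.1 ± 0.39 to 17.9 ± 2.14 CPM (SD, n = 3; log2 2.53, SE 0.21, adjusted p = 0.00032). Its exons overlap those of ERI2 on the opposite strand. The strandedness of the counting is not stated, so which gene such counts belong to is uncertain here and for each overlap named below. PDE4C, XPC, CYGB, GRIP2, PFKFB4, CYFIP2, TOMM6, TPI1 and MRPL9 also share exon positions with a neighbouring gene. INPP5D, a lipid phosphatase, rose by log2 2.28 (adjusted p = 0.00351). TXNIP (ENSG00000265972; chromosome 1, 145992435 to 145996600, GRCh38, GENCODE 29), which limits glucose uptake and binds thioredoxin, rose from 5.74 ± 1.28 to 22.6 ± 3.51 CPM (SD, n = 3; log2 1.97, SE 0.25, adjusted p = 0.00285). The other large rises were S100A1 (2.12, overlapping S100A13), MYO15B (1.93), APOLD1 (1.89, overlapping DDX47) and SEMA3G (1.73). The MYO15B call was lost without Pt-ttpy 1 (adjusted p = 0.0568), and the other 7 of these 8 calls held whichever library was left out.

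Among the 8 largest falls were the drug efflux gene ABCB1 and the genes ID2 and ID3, of a family whose proteins hold back differentiation factors. ABCB1 (ENSG00000085563; chromosome 7, 87503633 to 87713323), the multidrug efflux pump, fell from 6.33 ± 0.595 to 1.73 ± 0.304 CPM (SD, n = 3; log2 −1.87, SE 0.28, adjusted p = 0.00467). ID2 (ENSG00000115738; chromosome 2, 8678845 to 8684453) fell from 56.3 ± 2.95 to 19 ± 2.35 CPM (SD, n = 3; log2 −1.57, SE 0.15, adjusted p = 0.000799). ID3 fell from 355 ± 60.5 to 158 ± 16.9 CPM (log2 −1.16, adjusted p = 0.00252). TREX2 (−1.97, overlapping HAUS7), SURF2 (−1.16, overlapping SURF1), FRY (−1.14), DHRS2 (−1.14) and CCN1 (−1.13) completed the 8, and 5 of the 8 kept their call whichever library was left out. TREX2 lost it without Pt-ttpy 1 (adjusted p = 0.0643) or Pt-ttpy 2 (0.07). CCN1 lost it without DMSO 2 (0.0597), DMSO 3 (0.0609), Pt-ttpy 1 (0.0796), Pt-ttpy 2 (0.0859) or Pt-ttpy 3 (0.0861). DHRS2 lost it without the same libraries (0.0638, 0.0749, 0.0725, 0.113 and 0.077 in that order).

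Of the genes chosen in advance, some p53 targets were higher after Pt-ttpy and others were not called. CDKN1A (ENSG00000124762; chromosome 6, 36676460 to 36687339), which encodes the cell-cycle inhibitor p21, rose from 15.6 ± 1.23 to 32.3 ± 3.48 CPM (SD, n = 3; log2 1.05, SE 0.14, adjusted p = 0.00327). The stress cytokine gene GDF15 (ENSG00000130513; chromosome 19, 18374731 to 18389176) rose by 0.80 (SE 0.21, adjusted p = 0.0339). DDB2, a DNA damage sensor, rose by 0.65 (adjusted p = 0.0154). ATF3 rose by 1.53 (0.0445) and the telomere-protein gene POT1 by 0.65 (0.045). TWNK, the mitochondrial DNA helicase, fell by 0.70 (0.0154; exons overlapping MRPL43 on the opposite strand), MT2A, a metal-binding protein, by 0.84 (0.0229) and CCNB1, a mitotic cyclin, by 0.40 (0.0278). The p53 targets MDM2 (0.29, adjusted p = 0.212), BAX (−0.06, 0.78) and BBC3 (0.54, 0.0779) were not called. Of these 8 calls only that of CDKN1A held whichever library was left out. GDF15 lost its call without DMSO 1 (0.0888), DMSO 3 (0.104), Pt-ttpy 1 (0.108), Pt-ttpy 2 (0.126) or Pt-ttpy 3 (0.0725), and MT2A without DMSO 2 (0.0636), DMSO 3 (0.0562), Pt-ttpy 2 (0.0841) or Pt-ttpy 3 (0.0767). Without Pt-ttpy 1, 2 or 3, DDB2 had adjusted p of 0.0505, 0.0768 and 0.062, and TWNK 0.0762, 0.0642 and 0.067. CCNB1 lost its call without DMSO 2 (0.052) or without Pt-ttpy 1, 2 or 3 (0.112, 0.121 and 0.0797), and POT1 and ATF3 each lost theirs without any of 7 libraries (up to 0.147 and 0.136).

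Of the 36 gene lists tested, camera called 17 after Pt-ttpy against DMSO, 3 higher and 14 lower. With an estimated correlation between the genes of a list, camera called 0. Fry, a rotation test, called 17, of which 14 were among those of camera. By fry, G1/S (adjusted p = 0.33), G2/M (0.112) and factors of mitochondrial DNA (0.0856) were not called, while interferon response (0.0196) and epithelial markers (0.0275) were called higher and NF-kB (0.0282) lower. In the p53 target list 14 of 47 genes were higher, 0 lower and 33 not called, with 21 higher when adjusted over the list alone. The median was 0.31, with adjusted p = 1.4e-07 by camera and 0.293 with an estimated correlation. SPATA18, which acts in mitochondrial quality control, rose by 1.44 and TP53INP1, a p53 cofactor, by 1.10. In the hypoxia response list 9 of 23 genes were higher, 1 lower and 13 not called, with 11 higher and 1 lower over the list alone (median 0.57, camera adjusted p = 6.8e-07, and 0.293 with an estimated correlation). PDK1 (ENSG00000152256; chromosome 2, 172555373 to 172608669), which keeps pyruvate out of the mitochondrial citrate cycle, rose from 29.7 ± 8.25 to 91.6 ± 8.72 CPM (SD, n = 3; log2 1.63, SE 0.24, adjusted p = 0.00464). BNIP3, a receptor for the removal of mitochondria, rose from 89.6 ± 13.1 to 169 ± 22.7 CPM (log2 0.91, adjusted p = 0.00835). BNIP3 lost its call without Pt-ttpy 2 (0.0511), and PDK1, SPATA18 and TP53INP1 kept theirs whichever library was left out. The list's median without DMSO 2 and cisplatin 2, the libraries with a rising GC trend, was 0.53. The mean score of the hypoxia list against the DMSO mean varied among the controls, at 0.02, −0.34 and 0.32 in DMSO 1, 2 and 3. It was 0.81, 0.70 and 0.57 in Pt-ttpy 1, 2 and 3. In the fibroblast marker list 6 of 11 genes were higher and 5 not called, with 7 higher over the list alone (median 0.60, camera adjusted p = 5.5e-05, and 0.131 with an estimated correlation). LUM, a matrix proteoglycan, rose by 1.22 and COL3A1, a collagen, by 0.77.

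Some nuclear genes for mitochondrial protein synthesis and respiration were lower after Pt-ttpy. Over all genes the change fell with mean expression (Spearman rho −0.33), with a median of −0.10 in the highest of 5 bins of expression. The list tests did not match genes on expression. They therefore do not separate the small negative medians in this and the next paragraph from that trend. In the mitochondrial ribosomal protein list 26 of 77 genes were lower, 0 higher and 51 not called, with 44 lower over the list alone (median −0.35, camera adjusted p = 8.9e-12, and 0.293 with an estimated correlation). MRPS2 fell from 135 ± 21.4 to 88.8 ± 1.72 CPM (log2 −0.60; exons overlapping PIERCE1), and MRPL9 fell by 0.50. Of 41 subunits of complexes II to V 7 were lower and 34 not called, with 12 lower and 1 higher over the list alone (median −0.21, camera adjusted p = 2.6e-05, and 0.293 with an estimated correlation). The succinate dehydrogenase subunit SDHB fell by 0.60 and the complex III subunit UQCRFS1 by 0.50. Of 37 nuclear complex I subunits 5 were lower and 32 not called, with 10 lower over the list alone (median −0.19, camera adjusted p = 0.000321, and 0.307 with an estimated correlation), among them NDUFS6 (−0.53) and NDUFB9 (−0.48). The citrate cycle list had 5 of 22 lower and 17 not called, with 6 lower over the list alone (median −0.21, camera adjusted p = 0.00119, and 0.293 with an estimated correlation), among them CS (−0.53). Among mitochondrial chaperones and proteases 4 of 19 were lower (4 over the list alone) and 15 not called (median −0.17, camera adjusted p = 0.0147, and 0.293 with an estimated correlation), led by PHB1 (−0.62). Factors that copy and express mitochondrial DNA had 4 of 39 lower (4 over the list alone) and 35 not called (median −0.14, camera adjusted p = 0.0226, and 0.362 with an estimated correlation), among them ELAC2 (−0.56). The call of this last list was lost without DMSO 1 (adjusted p = 0.099, median −0.088), and the interval of its mean spanned 0 (−0.28 to 0.07). Without Pt-ttpy 1, 2 or 3 only 68, 42 and 87 genes were called lower over all genes, so most calls of lower members in these and the other lists were lost. Among the genes named here, SDHB, CS and PHB1 lost their call without Pt-ttpy 1 or 2 (highest adjusted p = 0.0542, 0.0719 and 0.0642), and MRPS2, MRPL9, UQCRFS1, NDUFB9, NDUFS6 and ELAC2 without any one of the 3 (0.0657, 0.0756, 0.0665, 0.0857, 0.117 and 0.0849). NDUFS6 lost it without DMSO 2 as well. With upper-quartile factors the list medians shrank to −0.069 for factors of mitochondrial DNA, −0.12 for complex I and −0.10 for mitochondrial chaperones.

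Some genes for ribosome assembly and protein folding were lower as well. In the ribosome biogenesis list 10 of 36 were lower and 26 not called, with 18 lower over the list alone (median −0.35, camera adjusted p = 1.4e-07, and 0.293 with an estimated correlation). NOP2, an rRNA methyltransferase, fell by 0.69 and RRP12 by 0.56. Heat shock and endoplasmic reticulum chaperones had 8 of 27 lower and 19 not called, with 12 lower and 1 higher over the list alone (median −0.25, camera adjusted p = 3.2e-05, and 0.293 with an estimated correlation), led by HSPA8 (−0.71). The lysosome and autophagy list had 9 of 39 lower and 30 not called, with 10 lower over the list alone (median −0.19, camera adjusted p = 0.000321, and 0.307 with an estimated correlation), among them the lysosomal enzymes NEU1 (−0.79) and CTSA (−0.75). In the G2/M list 6 of 40 were lower and 34 not called, with 10 lower over the list alone (median −0.14, camera adjusted p = 0.00932, and 0.457 with an estimated correlation), among them the mitotic kinases PLK1 (−0.56) and AURKA (−0.41). The interval of the list mean spanned 0 (−0.31 to 0.13). Of 49 G1/S genes 3 were lower and 46 not called, a share near that over all genes (1004 of 15558 lower). The G1/S list had 0 lower over the list alone (median −0.12, camera adjusted p = 0.0283, and 0.729 with an estimated correlation). Its call was lost without DMSO 2 (adjusted p = 0.148) or Pt-ttpy 1 (0.0773), with 7 libraries, leaving out DMSO 2 and cisplatin 2 (0.0822), and with a GC correction (0.0909), and the interval of its mean spanned 0 (−0.30 to 0.10). Shelterin and telomerase genes had 3 of 17 lower, 1 higher and 13 not called, with 7 lower and 1 higher over the list alone (median −0.27, camera adjusted p = 0.00428, and 0.293 with an estimated correlation). The snoRNP genes GAR1 (−0.62) and NHP2 (−0.47) fell, opposite to the rise of POT1. NRF2 targets had 6 of 24 lower and 18 not called, with 7 lower over the list alone (median −0.16, camera adjusted p = 0.0201, and 0.293 with an estimated correlation), led by OSGIN1 (−1.13). The call was lost with 7 libraries (adjusted p = 0.0682), and the interval of the list mean spanned 0 (−0.23 to 0.06). The list of metallothioneins and metal transporters had 3 of 16 lower and 13 not called, with 6 lower over the list alone (median −0.30, camera adjusted p = 0.0243, and 0.293 with an estimated correlation). MT1X (−0.96) and the zinc exporter SLC30A1 (−0.70) fell, and the call was lost without DMSO 1 (adjusted p = 0.0695) or with 7 libraries (0.0502). Of 115 further called genes among the first 4 of their list, 30 kept their call in all 9 fits, NEU1 and CTSA among them. HSPA8 lost it without Pt-ttpy 1 or 2 (highest adjusted p = 0.0665). NOP2, RRP12, PLK1, AURKA, GAR1, NHP2, OSGIN1, MT1X and SLC30A1 lost it without any one of the 3 Pt-ttpy libraries (highest adjusted p = 0.081, 0.0748, 0.102, 0.102, 0.0936, 0.109, 0.0722, 0.135 and 0.124). Without DMSO 2 the medians shrank to −0.17 for shelterin, −0.12 for lysosome, −0.098 for NRF2 and −0.077 for G1/S, and to nearly the same values with 7 libraries. The metallothionein median was −0.45 without DMSO 3. With upper-quartile factors the medians were −0.073 for G2/M, −0.054 for G1/S, −0.096 for NRF2 and −0.125 for lysosome, smaller but of the same sign. GAR1 lost its call without DMSO 3 too, NHP2 without DMSO 2, and MT1X and SLC30A1 without DMSO 1 or DMSO 3.

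The lists closest to G-quadruplex biology were not called after Pt-ttpy. Among genes with a described promoter G-quadruplex 1 was higher and 2 lower (adjusted p = 0.792), with MYC at −0.21 (adjusted p = 0.423), TERT at −0.27, VEGFA at 0.05 and BCL2 at 0.69 (0.269), none of them called. PDGFRB rose by 1.13 and HRAS fell by 0.56. Among G-quadruplex helicases and binders 1 was higher and 2 lower (adjusted p = 0.287), with WRN at 0.50. The glycolysis list, with 4 higher and 1 lower, was not called (adjusted p = 0.102), with a median of −0.004 although camera placed it upward. The sign of that median turned positive with upper-quartile factors (0.064). The list was called higher without DMSO 2 (adjusted p = 0.0139), cisplatin 3 (0.0409) or Pt-ttpy 1 (0.0301), and with the GC correction (0.0181). In the integrated stress response list 5 were higher and 2 lower, among them DDIT4 (1.58) and ATF5 (−0.84). Its median was −0.05, its mean 0.20 and camera's direction upward, and the median turned positive (0.015) with upper-quartile factors. The mitophagy list had 2 higher, led by BNIP3L (1.60), and 3 lower, among them MFN2 (−0.59), and the apoptosis list had 2 higher, BMF (2.15) and BIK (1.19), and 2 lower, among them BAK1 (−0.65). The apoptosis median was −0.10 and its mean 0.12. The other uncalled lists were NF-kB (1 higher, 4 lower), interferon response (4 higher, 1 lower), extracellular matrix (5 higher, 4 lower), cytosolic ribosomal proteins (3 higher, 1 lower), nucleotide excision repair (2 higher, 1 lower), mismatch and base excision repair (1 and 1), histones (1 and 1), homologous recombination (0), cholesterol synthesis (0), and epithelial, endothelial and leukocyte markers. Adjusted p of the lists not called ran from 0.0955 to 0.974. Of the genes named in these lists ATF5 and BNIP3L kept their call whichever library was left out. DDIT4 lost it without DMSO 2, Pt-ttpy 2 or Pt-ttpy 3 (highest adjusted p = 0.0577), and HRAS, MFN2, BMF and BAK1 without any one Pt-ttpy library (0.0984, 0.0624, 0.0642 and 0.0972). PDGFRB lost it without any DMSO or Pt-ttpy library (0.0948), BIK without these or cisplatin 3 (0.164), and WRN without DMSO 2 or 3, cisplatin 1 or 3, or any Pt-ttpy library (0.135).

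The comparison of cisplatin with DMSO gave the response to a platinum drug whose target is known to be DNA, as the reference for Pt-ttpy. Cisplatin raised 40 of 47 p53 targets and lowered part of the cell-cycle genes (17 of 40 for G2/M), of the glycolytic genes (12 of 23) and of the mitochondrial ribosomal genes (27 of 77). With an estimated correlation only the p53 list was called, against adjusted p = 0.291, 0.373 and 0.315 for these others. Cisplatin changed 3190 genes (20.5% of those tested), 1669 higher and 1521 lower, with 5465 at an unadjusted p under 0.05. At least 2-fold changes were found in 878 genes, 828 higher and 50 lower. Of the called loci 298 were newGene loci, 284 of them higher. With upper-quartile factors 1940 genes were higher and 913 lower, and with library totals alone 1995 were higher and 943 lower.

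In the p53 target list 40 of 47 genes were higher after cisplatin, 0 lower and 7 not called, with 44 higher over the list alone. The median was 0.99 (camera adjusted p = 2.5e-58, and 0.00487 with an estimated correlation), the only list that test called. CDKN1A rose from 15.6 ± 1.23 to 139 ± 23.4 CPM (SD, n = 3; log2 3.15, SE 0.15, adjusted p = 1.2e-06). GDF15 rose from 8.49 to 99.1 ± 20.3 CPM (log2 3.55, SE 0.23, adjusted p = 7.5e-06). MDM2, the ubiquitin ligase that limits p53, rose from 142 ± 24.5 to 318 ± 55.4 CPM (log2 1.17, adjusted p = 0.000641; exons overlapping the gene CPM). BAX, which opens the mitochondrial outer membrane in apoptosis, rose from 39 ± 5.56 to 71.5 ± 7.84 CPM (log2 0.88, adjusted p = 0.00142). BBC3 rose by 1.44 (0.000734), and the repair genes DDB2 and XPC rose by 1.45 (8.0e-05) and 0.87 (0.0018). The proliferation marker MKI67 fell by 0.56 (0.0157), CCNB1 by 0.49 (0.0084), TWNK by 0.58 (0.0182) and MT2A by 0.97 (0.00821). All 11 calls in this paragraph held whichever library was left out. Of the 12 called genes chosen in advance, the 1 not named in this paragraph lost its call in some fit.

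The largest rises after cisplatin were of genes near absent with DMSO. PDE4C counts were 559, 1230 and 605 with cisplatin. PLXNB3 counts were 0, 0 and 4 with DMSO and 169, 425 and 183 with cisplatin, so the fitted log2 changes of 7.48 and 7.47 depend on the prior count. INPP5D rose from 1.12 ± 0.369 to 43.7 ± 17.5 CPM (SD, n = 3; log2 5.27, SE 0.33, adjusted p = 5.9e-06). The globin genes MB (5.33) and CYGB (4.16), TSPAN1 (4.82), GRIP2 (4.37) and GRHL3 (4.29), an epithelial transcription factor, completed the 8, and all 8 calls held whichever library was left out. Among the 8 largest falls were ABCB1 (−2.43, adjusted p = 0.000418), JUN (−1.46, 0.00538), ID2 (−1.36, 0.00027), DHRS2 (−1.27) and ACTR5 (−1.24). TREX2 (−1.47) lost its call without DMSO 2 (0.0676) or cisplatin 1 (0.0576). TOMM6 had the largest fall (−3.27, 0.0397), with counts of 2279, 1056 and 2521 in DMSO and 138, 183 and 255 with cisplatin, and kept its call in only 2 of the 9 fits (highest adjusted p = 0.129). P2RX5-TAX1BP3 (−1.20), a readthrough locus whose exons overlap its neighbours, kept its call in 3 of the 9.

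Camera called 21 lists after cisplatin, 5 higher and 16 lower, against 1 with an estimated correlation and 21 by fry, of which 18 were among those of camera. By fry, G-quadruplex helicases (adjusted p = 0.0835), cholesterol synthesis (0.102) and cytosolic ribosomal proteins (0.15) were not called, while interferon response (0.0187) and histones (0.0394) were called higher and mismatch and base excision repair (0.0366) lower. Besides the p53 targets, markers of fibroblasts had 7 of 11 higher and 4 not called, with 8 higher over the list alone (median 0.68, camera adjusted p = 0.000273, and 0.105 with an estimated correlation), among them PDGFRB (1.29) and COL3A1 (0.93). In the extracellular matrix list 9 of 32 genes were higher, 2 lower and 21 not called, with 13 and 2 over the list alone (median 0.22, camera adjusted p = 0.00687, and 0.291 with an estimated correlation). ACTA2, smooth muscle actin, rose by 3.64, but its exons overlap those of the p53 target FAS on the opposite strand, and TAGLN rose by 1.32. The matrix median was 0.10 with 7 libraries. Only 5 of 18 epithelial markers could be tested, and 3 were higher and 2 not called, with 4 higher over the list alone (median 1.74, camera adjusted p = 0.00583, and 0.291 with an estimated correlation). KRT8, an epithelial keratin, rose from 0.0563 ± 0.0975 to 1.48 ± 0.411 CPM (log2 4.66, adjusted p = 0.00786), a level too low for the size of the fold to carry weight. Cytosolic ribosomal proteins had 15 of 76 higher (15 over the list alone), 0 lower and 61 not called (median 0.14, camera adjusted p = 0.0061, and 0.729 with an estimated correlation), among them RPL7 (0.61) and RPL22 (0.54). Ribosomal protein genes have many processed copies, whose sharing of counts is not known, and this call was lost without cisplatin 2 (adjusted p = 0.176, median 0.068). The median of the epithelial markers was 2.87 without DMSO 2. That of cytosolic ribosomal proteins was 0.22 with upper-quartile factors.

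Part of the cell-cycle genes fell after cisplatin in both phases listed. Over all genes the change after cisplatin also fell with mean expression (Spearman rho −0.39), with a median of −0.16 in the highest of 5 bins. The list tests did not match on expression, so small negative medians after cisplatin are not separated from that trend. In the G2/M list 17 of 40 were lower and 23 not called, with 20 lower over the list alone (median −0.33, camera adjusted p = 8.6e-07, and 0.291 with an estimated correlation), among them KIF4A (−0.63) and AURKA (−0.54). In the G1/S list 17 of 49 were lower and 32 not called, with 23 lower and 1 higher over the list alone (median −0.32, camera adjusted p = 8.6e-07, and 0.356 with an estimated correlation), among them the origin factor ORC1 (−0.66) and the ribonucleotide reductase subunit RRM2 (−0.64). In the glycolysis list 12 of 23 were lower, 1 higher and 10 not called, with 14 lower and 1 higher over the list alone (median −0.44, camera adjusted p = 0.000257, and 0.373 with an estimated correlation). TPI1 fell from a mean of 969 to 605 CPM (log2 −0.68), LDHA by 0.68 and GAPDH by 0.54, while the lactate exporter SLC16A3 rose by 0.78. Without DMSO 2 and cisplatin 2 the medians shrank to −0.21 for glycolysis (camera adjusted p = 0.00497) and −0.16 for G1/S (0.0001).

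Part of the mitochondrial and ribosome assembly genes were lower after cisplatin too. In the mitochondrial ribosomal protein list 27 of 77 were lower, 1 higher and 49 not called, with 34 lower and 3 higher over the list alone (median −0.29, camera adjusted p = 2.5e-07, and 0.315 with an estimated correlation), among them MRPS18A (−0.66) and MRPS15 (−0.52). Complexes II to V had 12 of 41 lower, 1 higher and 28 not called, with 16 lower and 1 higher over the list alone (median −0.26, camera adjusted p = 9.8e-05, and 0.291 with an estimated correlation), with SDHB at −0.64 and the ATP synthase inhibitor ATP5IF1 rising by 0.59. Complex I had 7 of 37 lower and 30 not called (7 over the list alone; median −0.19, camera adjusted p = 0.00221, and 0.356 with an estimated correlation), and the citrate cycle 6 of 22 lower, 2 higher and 14 not called (11 and 2 over the list alone; median −0.22, camera adjusted p = 0.00481, and 0.356 with an estimated correlation). Mitochondrial chaperones had 4 of 19 lower and 15 not called (7 over the list alone; median −0.24, camera adjusted p = 0.00887, and 0.291 with an estimated correlation). Factors of mitochondrial DNA had 6 of 39 lower, 1 higher and 32 not called (8 and 1 over the list alone; median −0.21, camera adjusted p = 0.0147, and 0.356 with an estimated correlation), the rise being of the p53-induced nucleotide reductase RRM2B (1.10). Without cisplatin 2 that call was lost (adjusted p = 0.0896), as with 7 libraries (0.075). Ribosome biogenesis had 12 of 36 lower and 24 not called (19 over the list alone; median −0.32, camera adjusted p = 4.8e-06, and 0.349 with an estimated correlation), among them NOP56 (−0.60) and RRS1 (−0.60). With 7 libraries the medians shrank to −0.20 for ribosome biogenesis, −0.14 for the citrate cycle and −0.13 for factors of mitochondrial DNA. That of complex I was −0.11 without DMSO 2. Upper-quartile factors gave medians of −0.11 for complex I, −0.14 for the citrate cycle and −0.13 for factors of mitochondrial DNA.

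Stress, lipid and telomere lists made up the rest of the calls after cisplatin. Heat shock and endoplasmic reticulum chaperones had 9 of 27 lower and 18 not called (12 over the list alone; median −0.33, camera adjusted p = 0.000184, and 0.291 with an estimated correlation), with HSPA8 at −0.76 and HSPA5 at −0.39. NRF2 targets had 8 of 24 lower and 16 not called (11 over the list alone; median −0.24, camera adjusted p = 0.0061, and 0.291 with an estimated correlation), among them FTL (−0.51) and SRXN1 (−0.45). Cholesterol synthesis had 6 of 24 lower, 1 higher and 17 not called (9 and 2 over the list alone; median −0.32, camera adjusted p = 0.00887, and 0.487 with an estimated correlation), with DHCR7 at −0.58 and TM7SF2 at 0.63, a call lost without cisplatin 2 (adjusted p = 0.097) or with 7 libraries (0.178). Shelterin and telomerase had 5 of 17 lower and 12 not called (7 over the list alone; median −0.20, camera adjusted p = 0.0147, and 0.356 with an estimated correlation), with GAR1 at −0.68 and ACD at −0.61, a call lost without DMSO 2 (adjusted p = 0.0588) or with 7 libraries (0.075). G-quadruplex helicases and binders had 5 of 28 lower and 23 not called (5 over the list alone; median −0.22, camera adjusted p = 0.034, and 0.419 with an estimated correlation), among them the nucleolar protein NCL (−0.45) and PARP1 (−0.40). This call was lost without DMSO 1 (adjusted p = 0.102) or cisplatin 2 (0.128). Metallothioneins and metal transporters had 3 of 16 lower and 13 not called (6 over the list alone; median −0.31, camera adjusted p = 0.0365, and 0.291 with an estimated correlation), with MT1X at −1.67 and the copper importer SLC31A1 at −0.40. Without DMSO 1 (0.061) or cisplatin 3 (0.0612), with 7 libraries (0.102) or with the GC correction (0.0941) this list was not called. Of 136 called genes among the first 4 of their list, 103 kept their call in all 9 fits. FTL lost it without cisplatin 1 (0.0536) or cisplatin 3 (0.0632), NCL without DMSO 1 (0.0514), TM7SF2 without DMSO 3 (0.0556) and SLC31A1 without DMSO 3 (0.0592) or cisplatin 1 (0.0512). The intervals of the list means spanned 0 for NRF2 (−0.23 to 0.06), cholesterol synthesis (−0.49 to 0.06), G-quadruplex helicases (−0.31 to 0.09), factors of mitochondrial DNA (−0.30 to 0.05) and cytosolic ribosomal proteins (−0.05 to 0.37). Medians shrank to −0.15 for cholesterol synthesis without cisplatin 2 (−0.11 with 7 libraries), to −0.098 for shelterin without DMSO 2 and to −0.089 for G-quadruplex helicases without cisplatin 2. Counts of metallothionein genes may be shared among near-identical copies. With upper-quartile factors the medians were −0.11 for shelterin, −0.16 for NRF2 and −0.14 for G-quadruplex helicases.

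Lists not called after cisplatin had adjusted p from 0.0622 to 0.928. The hypoxia response had 1 higher and 3 lower, among them SLC2A1 (−0.63), which the glycolysis list also holds, with a median of 0.01 although camera placed it downward. SLC2A1 lost its call without DMSO 3 (0.0618) or cisplatin 1 (0.0506). Genes with a described promoter G-quadruplex had 1 higher and 2 lower (adjusted p = 0.776). The apoptosis list had 5 higher, among them BBC3 and BAX, and 1 lower, with a median of −0.12 although camera placed it upward. Nucleotide excision repair had 4 higher, among them DDB2 and XPC, and 2 lower, and NF-kB 4 higher and 2 lower, both with a median of −0.11 and an upward direction by camera. The integrated stress response had 4 higher and 7 lower, with a median of −0.15 and a mean of 0.11, and was called lower without cisplatin 2 (adjusted p = 0.00311) and with 7 libraries (0.00237). Histones (6 higher), interferon response (4 higher, 3 lower), mitophagy (3 higher, 5 lower), lysosome (1 higher, 8 lower), homologous recombination (4 lower), mismatch and base excision repair (4 lower), endothelial markers (1 lower) and leukocyte markers completed these lists. The small negative medians of lysosome, homologous recombination, and mismatch and base excision repair turned positive when libraries were scaled by totals alone (0.0037, 0.033 and 0.022).

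**Figure D1:**
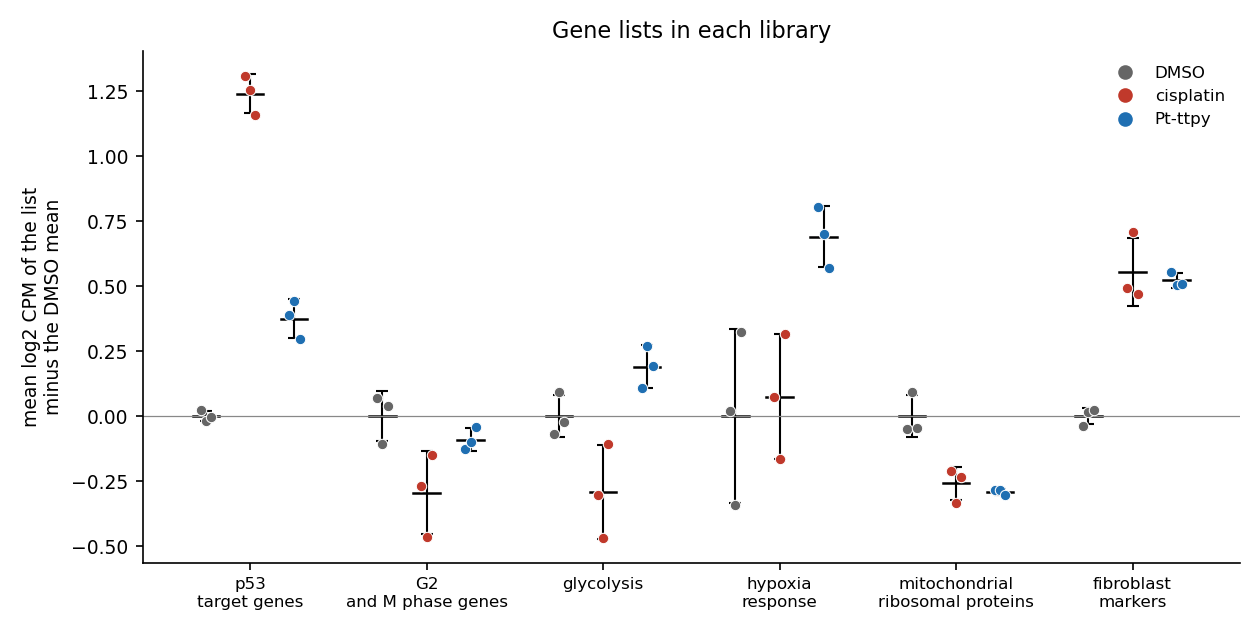
Mean log2 CPM of the genes of 6 lists in each library, minus the mean of the DMSO libraries. Points are libraries, and lines and bars give the mean and SD (n = 3).

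The direct comparison of Pt-ttpy with cisplatin asked which changes belong to one compound and not the other. Of 47 p53 targets, 22 were lower after Pt-ttpy than after cisplatin, and 6 of 23 glycolysis genes were higher. Of 23 hypoxia genes 3 were higher, all of them also members of the glycolysis list. The p53 list kept its call with an estimated correlation, and the other 2 lists lost it (adjusted p = 0.111 for each). The counts of higher genes did not hold in several fits with 1 library left out. Over all genes 0 were called higher without cisplatin 1 or Pt-ttpy 3, and 1 without Pt-ttpy 1 or Pt-ttpy 2. These fits leave 2 libraries in a group compared and have less power, so the losses need not trace to any 1 library. Fewer libraries did not always mean fewer calls, with 33 genes higher without DMSO 2. In all, 80 genes differed, 9 higher and 71 lower, and 1254 had an unadjusted p under 0.05. The one-sided division depended on the fit, with 371 higher and 442 lower with 7 libraries and 56 higher and 153 lower with the GC correction. At least 2-fold differences were found in 43 genes, 2 higher and 41 lower, and 2 newGene loci were among the lower. The doses differed, 5.5 µM of Pt-ttpy against 0.6 µM of cisplatin, each labelled as the IC80 of its drug. A difference may come from the compound or from the dose.

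In the p53 target list 22 of 47 genes were lower after Pt-ttpy than after cisplatin, 0 higher and 25 not called, with 40 lower over the list alone. The median difference was −0.80 and the mean −0.87 (95% interval −0.99 to −0.74), with adjusted p = 8.4e-103 by camera and 0.000556 with an estimated correlation. The mean score of the list against DMSO was 0.39, 0.44 and 0.30 in the 3 Pt-ttpy libraries and 1.31, 1.26 and 1.16 in the 3 cisplatin libraries. CDKN1A stood at 32.3 ± 3.48 CPM with Pt-ttpy and 139 ± 23.4 with cisplatin (SD, n = 3; log2 −2.10, SE 0.14, adjusted p = 7.6e-05). GDF15 differed by −2.75 (0.000254), BTG2, an antiproliferative gene, by −1.36 (0.000298) and CYFIP2 by −1.66 (0.000605). BAX (−0.94, 0.00707), MDM2 (−0.88, 0.0241) and DDB2 (−0.80, 0.0241) were lower, and BBC3 (−0.90, 0.0616), XPC (−0.62, 0.0695) and ATF3 (1.33, 0.375) were not called. The call of BAX was lost without Pt-ttpy 1, 2 or 3 (adjusted p = 0.0607, 0.0592 and 0.0791). Among the largest falls were INPP5D (−2.99, 0.000605), GDF15, PLXNB3 (−2.68; counts 38, 43 and 30 with Pt-ttpy), RINL (−2.47), GRIP2 (−2.28), CYGB (−2.28) and CDKN1A. Of these, CDKN1A, GDF15 and INPP5D kept their call whichever library was left out. MDM2, DDB2, PLXNB3, RINL, GRIP2 and CYGB lost theirs without any one of the 3 Pt-ttpy libraries (highest adjusted p = 0.159, 0.165, 0.155, 0.159, 0.141 and 0.11). MDM2 was also not called without cisplatin 1 (0.103) or cisplatin 3 (0.0677). Without cisplatin 1 or 2, DDB2 (0.0647 and 0.0598), PLXNB3 (0.0511 and 0.0809), RINL (0.0566 and 0.0634) and GRIP2 (0.0566 and 0.0598) were not called either.

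Some genes that feed glycolysis were higher after Pt-ttpy than after cisplatin. Against DMSO the glycolysis median was −0.004 after Pt-ttpy and −0.44 after cisplatin, so by the medians the difference lay in a fall after cisplatin. The hypoxia medians were 0.57 and 0.01. Of the genes named below, PDK1 (1.63), PFKFB4 (0.87) and ALDOC (0.80) stood above DMSO after Pt-ttpy, while SLC2A1 (−0.63) and HK2 (−0.50) stood below it after cisplatin. In the glycolysis list 6 of 23 were higher, 0 lower and 17 not called, with 17 higher over the list alone. The median was 0.41 and the mean 0.48 (95% interval 0.24 to 0.73), with adjusted p = 1.8e-24 by camera and 0.111 with an estimated correlation. In the hypoxia response list 3 of 23 were higher and 20 not called, with 16 higher over the list alone. Its median was 0.61 and its mean 0.62 (95% interval 0.12 to 1.11), with adjusted p = 3.0e-21 by camera and 0.111 with an estimated correlation. The 3 hypoxia genes called, PDK1, SLC2A1 and PFKFB4, are members of the glycolysis list too. No called gene therefore belonged to the hypoxia list alone. PDK1 stood at 91.6 ± 8.72 CPM with Pt-ttpy and 35.8 ± 11.9 with cisplatin (SD, n = 3; log2 1.36, SE 0.24, adjusted p = 0.0301). SLC2A1 (ENSG00000117394; chromosome 1, 42925375 to 42959176), the main glucose importer, stood at 150 ± 16.3 and 77.9 ± 21.2 CPM (SD, n = 3; log2 0.95, SE 0.17, adjusted p = 0.0301). The hexokinase HK2 (0.79, 0.0367), PFKFB4 (0.91, 0.0347), a regulator of phosphofructokinase, and the aldolase ALDOC (0.86, 0.0213) were higher as well. RIMKLA (1.68, 0.0419), the glutamate transporter SLC1A1 (0.90, 0.0241) and REEP1 (0.89) completed the 8 largest rises. Without Pt-ttpy 1, 2 or 3 all 8 lost their call (adjusted p from 0.071 to 0.237) and stayed positive (0.63 to 2.14). All 8 also lost it without cisplatin 1, with adjusted p from 0.0647 for REEP1 to 0.189 for RIMKLA, and each lost it without cisplatin 2, cisplatin 3 or a DMSO library as well. Without DMSO 2 and cisplatin 2 the list medians were 0.32 for glycolysis and 0.42 for hypoxia.

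**Figure D2:**
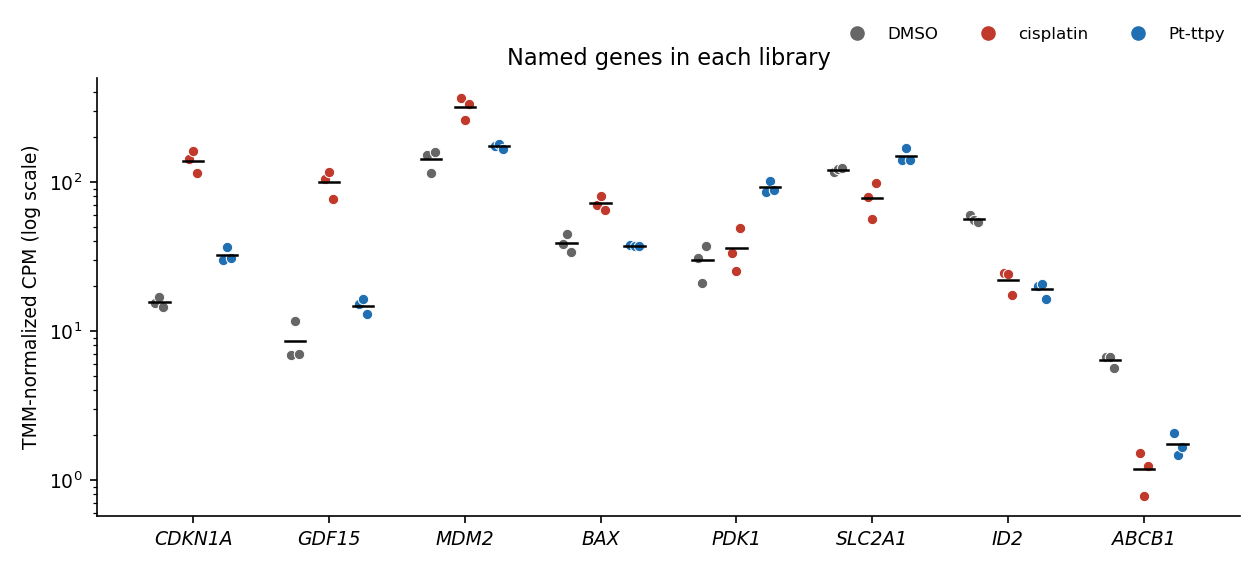
Normalised counts (CPM) of 8 genes named in the text, on a log axis. Points are libraries and lines are group means.

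Camera called 13 lists between the compounds, 6 higher and 7 lower, against 1 with an estimated correlation (p53 targets) and 5 by fry. By fry the calls of G1/S, G2/M, homologous recombination, cholesterol synthesis, cytosolic ribosomal proteins, lysosome, histones and epithelial markers were lost (adjusted p = 0.221, 0.15, 0.285, 0.392, 0.473, 0.392, 0.147 and 0.0834). For all of these but epithelial markers the interval of the list mean spanned 0, as −0.02 to 0.42 for G2/M and −0.01 to 0.39 for G1/S. Camera placed the 2 cell-cycle lists and homologous recombination higher with Pt-ttpy, although 0 of their genes were called over all genes. The medians were 0.16 for G1/S (camera adjusted p = 2.8e-08, and 0.503 with an estimated correlation), 0.17 for G2/M (2.1e-06, and 0.36 with an estimated correlation) and 0.20 for homologous recombination (3.0e-05, and 0.392 with an estimated correlation). With 7 libraries they shrank to 0.081, 0.098 and 0.11, and without cisplatin 2 alone to 0.082, 0.099 and 0.11. Cholesterol synthesis had a median of 0.18 (0.000368, and 0.587 with an estimated correlation), a call lost without cisplatin 2 (adjusted p = 0.204) or with 7 libraries (0.0713), with medians of 0.064 and 0.063, against 0.30 without cisplatin 3. The extracellular matrix list had 2 genes lower, 3 over the list alone (median −0.12, camera adjusted p = 0.00032, and 0.176 with an estimated correlation), namely ACTA2 (−1.96) and TAGLN (−1.70). TAGLN lost its call without Pt-ttpy 1, 2 or 3 (0.0706, 0.074 and 0.0909), and ACTA2 kept it. The matrix median was −0.041 with 7 libraries, −0.040 without cisplatin 2 and −0.19 without cisplatin 1. NF-kB targets had 2 lower, 3 over the list alone (median −0.25, or −0.15 with the GC correction, camera adjusted p = 0.000479, and 0.152 with an estimated correlation), among them the cytokine gene LIF (−1.06), which kept its call in only 1 of the 9 fits (highest adjusted p = 0.255). Cytosolic ribosomal proteins had a median of −0.11 (0.00011, and 0.786 with an estimated correlation; lost without cisplatin 2, 0.327, or with 7 libraries, 0.251) and histones of −0.39 (0.00144, and 0.482 with an estimated correlation; lost without cisplatin 1, 0.0861). Epithelial markers had a median of −1.37, with 1 of 5 lower over the list alone (0.00622, and 0.161 with an estimated correlation), a call lost with 7 libraries (0.0574). The lysosome list (−0.08, 0.0382, and 0.669 with an estimated correlation) lost its call without DMSO 3 (0.051), cisplatin 1 (0.0861), cisplatin 2 (0.0556), cisplatin 3 (0.0688) or Pt-ttpy 1 (0.179), or with the GC correction (0.121, median −0.03). The ribosomal protein median was −0.036 without cisplatin 2, −0.037 with 7 libraries and −0.19 without cisplatin 3, and that of histones −0.21 without Pt-ttpy 3.

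For the nuclear mitochondrial lists camera called no difference between the compounds with all 9 libraries. The mean difference, Pt-ttpy minus cisplatin, was −0.03 for mitochondrial ribosomal proteins (95% interval −0.15 to 0.09, camera adjusted p = 0.417), although that list was called lower without cisplatin 2 (adjusted p = 0.0171) and with 7 libraries (0.00346). It was 0.00 for complex I (−0.12 to 0.13), 0.02 for complexes II to V (−0.09 to 0.13), 0.00 for the citrate cycle (−0.09 to 0.10) and 0.03 for factors of mitochondrial DNA (−0.15 to 0.20). Ribosome biogenesis stood at 0.00 (−0.21 to 0.22), and was called lower without cisplatin 2 (adjusted p = 0.0113) and with 7 libraries (0.00055). The mean difference was for heat shock chaperones 0.02 (−0.07 to 0.11), for fibroblast markers −0.03 (−0.19 to 0.13), for shelterin −0.01 (−0.11 to 0.10) and for metallothioneins −0.07 (−0.23 to 0.09). The 6 leukocyte markers tested had a larger mean difference with a wide interval (0.67, −0.23 to 1.58). Genes with a described promoter G-quadruplex stood at 0.02 (−0.10 to 0.15), and G-quadruplex helicases were not called (adjusted p = 0.0601). Nucleotide excision repair, apoptosis and the integrated stress response had 1 gene lower each and were not called, the last (adjusted p = 0.207) being called higher without cisplatin 2 (6.1e-10) and with 7 libraries (2.4e-11). NRF2 targets were called with 7 libraries (0.0338). Adjusted p of the uncalled lists, which also held NRF2, mitophagy, interferon, mismatch repair, mitochondrial chaperone, endothelial and leukocyte lists with 0 genes called, ran up to 0.952. The small medians of 7 uncalled lists, among them complexes II to V, NRF2 and ribosome biogenesis, changed sign with the scaling of the libraries.

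The 2 responses were then set side by side, to see how far Pt-ttpy repeats the pattern of cisplatin. Of the 1874 genes changed by Pt-ttpy, 1485 (79.2%) also changed with cisplatin in the same direction, 677 higher and 808 lower, and 0 changed in opposite directions. Independent lists of these sizes would share 93.3 higher, 98.2 lower and 193 opposite. Across the 15558 genes the log2 changes against DMSO had a Pearson correlation of 0.79 and a Spearman correlation of 0.79. Both comparisons use the same 3 DMSO libraries, which alone gave 0.50 and 0.45 in 20 simulations without drug effects, and shared calls of 0.05 higher and 0.05 lower. The covariance was 0.41 against 0.083 simulated, a difference of 0.33. With 3 controls that cannot be divided between the comparisons, part of this excess may come from the shared controls. The sample records give 0.5% DMSO for the controls and no DMSO level for the treated libraries. A difference in vehicle would enter both comparisons alike and could not be told apart from the drugs. Genes called in both included CDKN1A, ABCB1, ID2, INPP5D and SDHB.

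**Figure D3:**
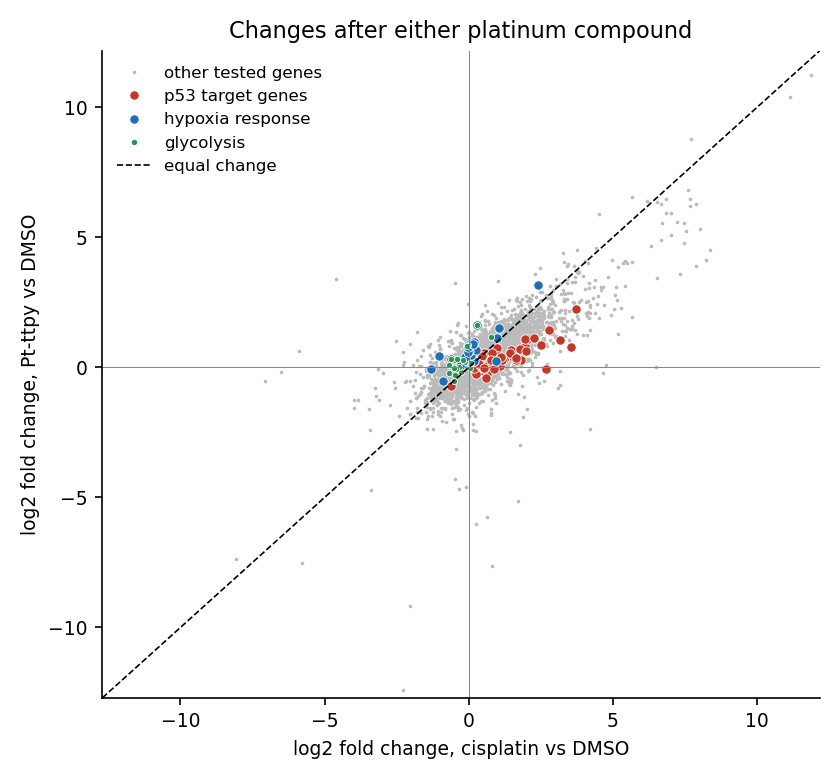
Fitted log2 changes of all tested genes after cisplatin (horizontal) and Pt-ttpy (vertical), each against DMSO. p53 targets lie mostly below the line of equal change, and hypoxia and glycolysis genes mostly above it.

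The mitochondrial genome was examined because the title places Pt-ttpy's effect partly in mitochondria. The table held the 13 protein-coding genes of mitochondrial DNA and no mitochondrial rRNA. Their share of counts was 1.75%, 1.81% and 1.89% in the DMSO libraries (mean 1.82% ± 0.0669, SD, n = 3). It was 4.21%, 0.756% and 2.03% with cisplatin (2.33% ± 1.75, SD, n = 3) and 4.18%, 1.95% and 2.07% with Pt-ttpy (2.73% ± 1.25, SD, n = 3). The exact binomial 95% interval of the lowest share, in cisplatin 2, was 0.754% to 0.759%, which covers counting error only. By a two-sided exact permutation test Pt-ttpy differed from DMSO by 0.915 points (p = 0.1, the smallest that 3 against 3 allows, and 0.3 adjusted over the 3 comparisons). By the same exact permutation test cisplatin differed from DMSO by 0.514 points (p = 0.7, adjusted 0.8) and Pt-ttpy from cisplatin by 0.401 points (p = 0.8, adjusted 0.8). None of the 13 genes was called in any comparison by edgeR, with MT-CO1 at 0.68 after Pt-ttpy and 0.53 after cisplatin. Camera did not call them as a list (adjusted p = 0.363 for Pt-ttpy, 0.928 for cisplatin and 0.128 between the compounds). For cisplatin the median was 0.39 but the mean −0.13 and camera's direction downward, and between the compounds the mean was 0.57 (95% interval −1.24 to 2.37). TFAM (−0.11 after Pt-ttpy), POLG and POLRMT, which package, copy and transcribe mitochondrial DNA, were not called after Pt-ttpy.

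Single libraries decided the mitochondrial values. Without Pt-ttpy 1 the difference between Pt-ttpy and DMSO fell to 0.192 points. Cisplatin minus DMSO was −0.425 without cisplatin 1 and 1.30 without cisplatin 2. Pt-ttpy minus cisplatin was −0.387 without cisplatin 2, −0.321 without Pt-ttpy 1, 1.34 without cisplatin 1, 0.25 without cisplatin 3, 0.792 without Pt-ttpy 2 and 0.733 without Pt-ttpy 3. The list of the 13 genes was called higher with Pt-ttpy than with cisplatin when cisplatin 1 (adjusted p = 1.2e-07), Pt-ttpy 2 (0.0181) or Pt-ttpy 3 (0.0281) was left out. In cisplatin 2 all 13 genes were below the DMSO mean, from −3.27 for MT-ND3, a complex I gene, to −0.58 for MT-CO1. All 13 were above it in cisplatin 1 (0.51 to 1.55) and Pt-ttpy 1 (0.63 to 1.51). In each of these libraries the 13 transcripts thus moved in the same direction, by unequal amounts.

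**Figure D4:**
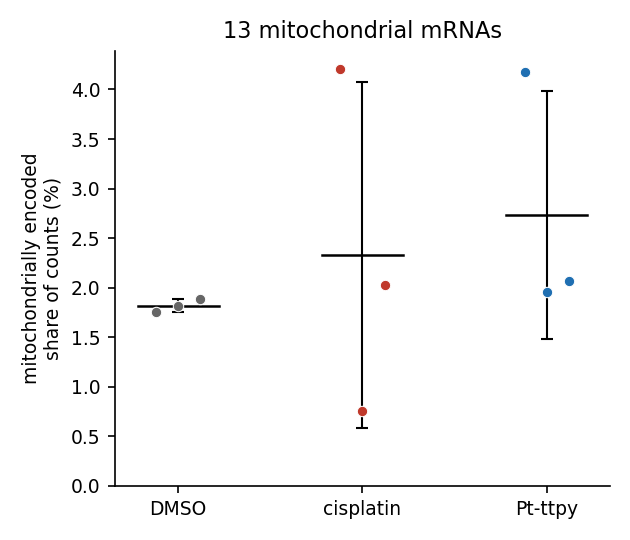
Share of each library's counts in the 13 protein-coding genes of mitochondrial DNA. Points are libraries, and lines and bars give the mean and SD (n = 3).

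Gene length was compared with the change because platinum adducts block transcription, which would lower long genes most. Longer genes did not fall more, with a Spearman rho of genomic length and log2 change of 0.061 for cisplatin and 0.19 for Pt-ttpy. With the GC correction rho was 0.074 for cisplatin and 0.12 for Pt-ttpy. Within 5 equal bins of mean expression rho ran from −0.03 to 0.22 for cisplatin and from 0.06 to 0.36 for Pt-ttpy, and between the compounds it was 0.24, or 0.0887 with the GC correction. Weakly expressed genes rose more, with a median of 0.51 in the lowest and −0.16 in the highest bin after cisplatin, and 0.37 and −0.10 after Pt-ttpy. The rho of transcript GC content with the change was −0.21 for Pt-ttpy, 0.02 for cisplatin and −0.44 between the compounds.

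The data could show large changes and miss small ones. In counts simulated with 200 changed genes among 15558, the fit recovered 64.2% of 2-fold changes for Pt-ttpy against DMSO, and 59.7% for the other comparisons. At 1.5-fold it recovered 22.4% and 19.4%. Of its calls 5.74%, 6.61% and 5.98% were false in the 3 comparisons. The simulation planted 200 changes and no GC trend, while the real comparisons with DMSO called 1874 and 3190 genes. Its rates of recovery and of false calls therefore need not hold for these data. Camera called 0 of 30 lists without a planted change and found the planted list. The simulated genes varied independently of each other. These runs therefore cannot show how often camera calls lists whose genes are correlated.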

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

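The fits on 7 libraries, with a GC correction and without newGene loci were chosen only after the GC trend and the loci had been seen, and all other alternatives were planned. The count of genes changed by Pt-ttpy ran from 185 to 3004 when 1 library was left out (1874 with all). It was lowest without Pt-ttpy 2 (185), Pt-ttpy 1 (267) or Pt-ttpy 3 (299), was 1150 without DMSO 3 and highest without cisplatin 2. It was 5189 with 7 libraries, 3633 with the GC correction, 2834 by DESeq2, 196 at an adjusted p under 0.01 and 374 at 2-fold or more. For cisplatin the range was 2012 to 3100 (2012 without cisplatin 2, 2031 without DMSO 3), with 5272 under the GC correction, 1313 with only the 6 libraries compared, 949 at an adjusted p under 0.01 and 878 at 2-fold. Between the compounds the range was 18 to 155. It was 18 without Pt-ttpy 1 or 3, 21 without Pt-ttpy 2, 36 without cisplatin 1 and 155 without DMSO 2. It was 813 with 7 libraries, 209 with the GC correction, 253 by DESeq2, 24 at an adjusted p under 0.01 and 43 at 2-fold. With 7 libraries 1851 of 1874, 2816 of 3190 and 77 of 80 calls were kept. Lists called ran from 15 to 18, 20 to 22 and 12 to 14 with 1 library left out. They were 0, 1 and 1 with an estimated correlation, and 5 by fry between the compounds. Genes shared by both drugs were 3028 with the GC correction and 3518 with 7 libraries, and the correlation stayed between 0.79 and 0.81 without any 1 control. The mitochondrial share differences ran from 0.192 to 1.31 (Pt-ttpy vs DMSO), −0.425 to 1.30 (cisplatin vs DMSO) and −0.387 to 1.34 (Pt-ttpy vs cisplatin). The rho of gene length between the compounds was 0.0887 with the GC correction. Results that turned direction and were called were the 13 mitochondrial genes after cisplatin without cisplatin 2 (direction by camera, from down to up, with a median of 0.39 with all libraries and 0.87 without it, adjusted p = 0.0452; −0.46 to 0.87 over all libraries left out), TFAM between the compounds with 7 libraries (−0.22, 0.0283), and ribosome biogenesis between the compounds without cisplatin 2 (−0.11, 0.0113) or with 7 libraries (−0.12, 0.00055), with −0.11 to 0.048 over all libraries left out. The cause was not tested. With the replicate number as a block the calls were 2539, 3712 and 140, and 1930 were shared. Whether libraries of the same number share a batch was not settled. The correlation of their deviations was above 0.1 in 1 of 9 pairs (range −0.039 to 0.22), but 6 of 9 libraries correlated best with their own number. DMSO 2 and cisplatin 2 shared the rising GC trend, which Pt-ttpy 2 lacked. Cisplatin 1 and Pt-ttpy 1 shared the highest mitochondrial shares (4.21% and 4.18%), against 1.75% in DMSO 1. The motif test was not run, for lack of a genome sequence. Leaving out mitochondrial rRNA changes nothing, since the table holds none.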

Other observations

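The tests of whether the 13 mitochondrial transcripts scaled alike and of the loss of short transcripts were chosen only after the result was seen. So were the fits with 7 libraries and the GC correction. The p53, hypoxia, glycolysis and mitochondrial patterns, and the 3 libraries examined for the last, were picked from these same data. The tests of these patterns were therefore not fixed before the data were seen. The smaller p53 response to Pt-ttpy could be part of a response that is weaker throughout. Against 10000 lists matched on the cisplatin change and expression, 0 had a median difference as low as that of the p53 targets (percentile 0). The list stood at −0.80 and matched lists at −0.27 (95% of lists −0.39 to −0.17). A uniformly weaker response may therefore explain only part of the gap. The matched genes were drawn independently, so that range leaves out the correlation between p53 targets. Matching was on the fitted cisplatin change, which carries the error of the same libraries. GC-dependent counts are an unlikely source, with a median of −0.75 after the GC correction and −0.77 with 7 libraries. Drug and dose differ together and could not be told apart, although the labels place each drug at its IC80 and all libraries at 96 h.

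GC-dependent counts were weighed as a source of the higher hypoxia and glycolysis lists with Pt-ttpy than with cisplatin. For glycolysis the medians against DMSO were −0.004 after Pt-ttpy and −0.44 after cisplatin, so that difference lay in a fall after cisplatin. With the GC correction the median moved from 0.61 to 0.57 for hypoxia and rose from 0.41 to 0.47 for glycolysis. These values argue against the GC trend as the main source. With 7 libraries the medians were smaller, 0.42 and 0.32, so leaving out DMSO 2 and cisplatin 2 took away part of the difference. A difference in oxygen, medium use or cell density at 96 h could shift the same genes and was not tested.

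The spread of the mitochondrial share among treated libraries might reflect library chemistry instead of the drugs. In cisplatin 1 and 2 and Pt-ttpy 1, the 3 libraries farthest from DMSO, nuclear genes of the same GC content (1040 genes) moved at most 0.0852 times as far as the mitochondrial genes (0.354 and 0.471 times in Pt-ttpy 2 and 3, where those moved little), so GC content is an unlikely cause in these 3. Nor did all 13 transcripts scale alike, since the smallest SD over them in the same 3 libraries was 0.309, against at most 0.103 in DMSO. In cisplatin 2 the shorter genes were lower (rho with gene length 0.56, two-sided permutation p = 0.0489, 13 genes). This is a borderline value from genes that are not independent. It may point to loss of short transcripts in that library, although the length of the RNA molecules themselves was not examined. Cisplatin 1 and Pt-ttpy 1, which had the highest shares, carry the same replicate number, while DMSO 1 had no such rise. Differences in RNA handling or batch between the libraries were not tested.

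Length and grouping were tested for all comparisons. Loss of long genes to platinum adducts is an unlikely general cause of these changes, since the rho of length with the change was 0.0609 for cisplatin and 0.191 for Pt-ttpy. Among the 10 splits of 6 libraries into 3 and 3, which cannot give a share under 0.05, 1 of 10 had as many changed genes in each comparison, the real one. It gave 2217, 1313 and 77 genes for Pt-ttpy vs DMSO, cisplatin vs DMSO and Pt-ttpy vs cisplatin, and the highest other gave 5, 2 and 1.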
